A study of Mus musculus with 6 samples.

How the data were processed

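Total RNA from iKAP primary cultured mouse cells was measured on 6 Affymetrix 3' expression arrays with a biotin label. iKAP names a mouse colorectal cancer model that carries engineered alleles, Apc among them. Per the labels' protocols, the cells were grown in DMEM with a tetracycline-free additive and RNA was extracted with Trizol. Per the series' design text, either the IRF2 open reading frame or GFP was stably expressed from a lentiviral plasmid. The sample titles place 3 arrays in the IRF2 group and 3 in the GFP control group, each numbered 1 to 3. No label says whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

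The deposited values are linear probe set intensities, one per probe set and array, for 45101 probe sets. MAS5 is named in the submitters' processing notes, with no role or version; whether it made all of these values is not given in the sources used here. The deposited intensities run from 2.59 to 14181 with no missing value. The medians of the 6 arrays lie between 18.2 and 18.7, so the arrays already shared a scale, and no further scaling was applied. Their 2% trimmed means run from 116 to 118 and are not equal. The arrays were thus not last scaled to a common value of this mean over all these probe sets. Any other scaling stays open. No detection calls were used here, so a low intensity is described by its level alone. The 3 tryptophan control probe sets of the array, which no mouse transcript should fill, read between 3.69 and 6.52 over the 6 arrays.

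Probe sets were named from GEO's platform annotation. Of the 45037 probe sets that are not array controls, 34945 had 1 gene symbol, 932 had several and were left unnamed, and 9160 had none in that annotation. The gene number of 34741 of the named probe sets was found in a RefSeq gene table of GRCm38.p6, which was used only for symbols, synonyms, gene length and the order of genes along chromosomes. No probe sequences were used, so the part of a transcript that a probe set reads is not stated. Where a gene had several probe sets, the one with the highest mean log2 value over all 6 arrays stood for it. Of 18193 genes, those whose probe set had a mean at or under the 40th percentile of all non-control probe sets (an intensity of 11.3) were left out, which left 12795 genes.

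The log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with the group as the only term and all 6 arrays in the fit, which leaves 4 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. Every adjusted p below comes from this fit unless another test is named. A change is given as the log2 fold change, IRF2 over GFP control, with its standard error (SE). Levels are mean intensities with the SD over 3 arrays. The number of arrays limits the precision; the median within-group SD on the log2 scale fell from 0.12 for probe sets of the fourth intensity decile to 0.03 for the brightest decile.

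Before the data were examined, 20 gene lists, the test, the filter, the alternatives and the rule for named genes were fixed. The rule took every probe set of Irf2, the engineered genes, the interferon regulatory factors, the CXCR2 ligands, the 15 genes with the largest rise and the 15 with the largest fall among genes past the threshold whose groups did not overlap (clone and model names left out), and up to 4 members of each list with the smallest p. Not every gene that the rule takes is reported here. Genes named outside this rule are further members of the fixed lists, given to describe a list, or are said to have been chosen after their values were seen. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 20 lists, with an estimated correlation beside it, and with fry, which asks whether a list's genes move one way without comparing them with other genes. Of the 7 lists called at the preset correlation, 1 was called with an estimated correlation. With an estimated correlation, camera also uses the 4 residual degrees of freedom, far fewer than at the preset correlation. A call lost this way need not reflect correlated members. The interferon gamma-induced list had an estimated correlation of -0.034, under the preset 0.01, yet its unadjusted camera p rose from 0.00621 to 0.0449.

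The fit was tested on simulated data with the real means and spreads, for the IRF2 against GFP control comparison over 12795 genes with 200 changed genes. It recovered 55.7% of changes of 0.2 on the log2 scale, 98.3% of changes of 0.5 and 100% of changes of 1, and 5.20% of its calls were false. With no change simulated, it called 0 genes and 0 lists. The simulated noise was independent between genes, so it does not show how often correlated genes make camera call a list. The simulation also changed far fewer genes than the 4642 called in the data.

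The alternatives were no filter and a filter at the 60th percentile, quantile normalization, median centring, log2(value + 16), the mean of a gene's probe sets, each probe set on its own, eBayes without the trend or with robust settings, array weights, the replicate number as a block, and leaving out each array in turn. The mean of a gene's probe sets also takes in those under the intensity filter. No array was left out. All pairs of arrays within a group correlated at 0.9981 or more over probe sets, and pairs across groups at 0.9965 or less; no 2 arrays held the same values.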

Results

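Gene expression was compared between iKAP mouse colorectal cancer cells labelled as carrying an IRF2 open reading frame and the same cells labelled as carrying GFP, with 3 arrays in each group. IRF2 is a transcription factor of the interferon regulatory factor family, and the study is known to have asked how it acts on the genes of these tumour cells, the chemokine Cxcl3 among them. The number of arrays limits the precision.

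The gene that the labels name was examined first. The only probe set named to Irf2 alone read 62.6 ± 2.53 (SD, n = 3) on the GFP control arrays and 36.3 ± 0.934 (SD, n = 3) on the arrays labelled IRF2, a log2 fold change of -0.79 (SE 0.06, limma adjusted p = 1.73e-07). Its direction goes against the label. The part of the transcript this probe set reads and the species of the open reading frame are not given in the sources used here, so a transgene that the probe set cannot see is not excluded, and the group is called "labelled IRF2" throughout. Of the other measured members of the family and its cofactors, Irf9, which joins the STAT proteins in interferon signalling, rose by 0.47 (SE 0.07), Irf7 by 0.42 (SE 0.10; 0.19 with 16 added before the log) and the IRF2-binding protein gene Irf2bpl by 0.36 (SE 0.04). Irf1 differed by 0.08 (SE 0.05, adjusted p = 0.205), and 5 of the 9 measured members did not pass the test. Camera gave this list an adjusted p of 0.304. Apc, one of the engineered genes, was higher by 0.11 (SE 0.03, adjusted p = 0.00961), but by 0.02 with an adjusted p of 0.754 in the mean of its probe sets (range over all alternatives 0.00187 to 0.754). That mean takes in all 4 of its probe sets. The 3 above the intensity filter ran from 0.05 to 0.11.

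Between the groups, 2111 of 12795 genes were higher on the arrays labelled IRF2 and 2531 were lower at an adjusted p under 0.05. Most of these differences were small: 3000 of the 4642 genes differed by less than 1.2-fold, and 56 genes were at least 2-fold higher and 37 at least 2-fold lower. The 3 arrays of each group did not overlap in 46.2% of the genes tested, where chance gives 10%. Among the RNA quality controls, the ratio of the 3' to the 5' beta-actin probe set lay between 0.996 and 1.02 over the 6 arrays. That ratio for the transferrin receptor was 3.61 to 3.78 on the GFP control arrays and 3.81 to 4.47 on the arrays labelled IRF2, and the 18S rRNA probe set read 1798 to 2034.5 and 2099 to 2254.5.

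**Figure D1:**
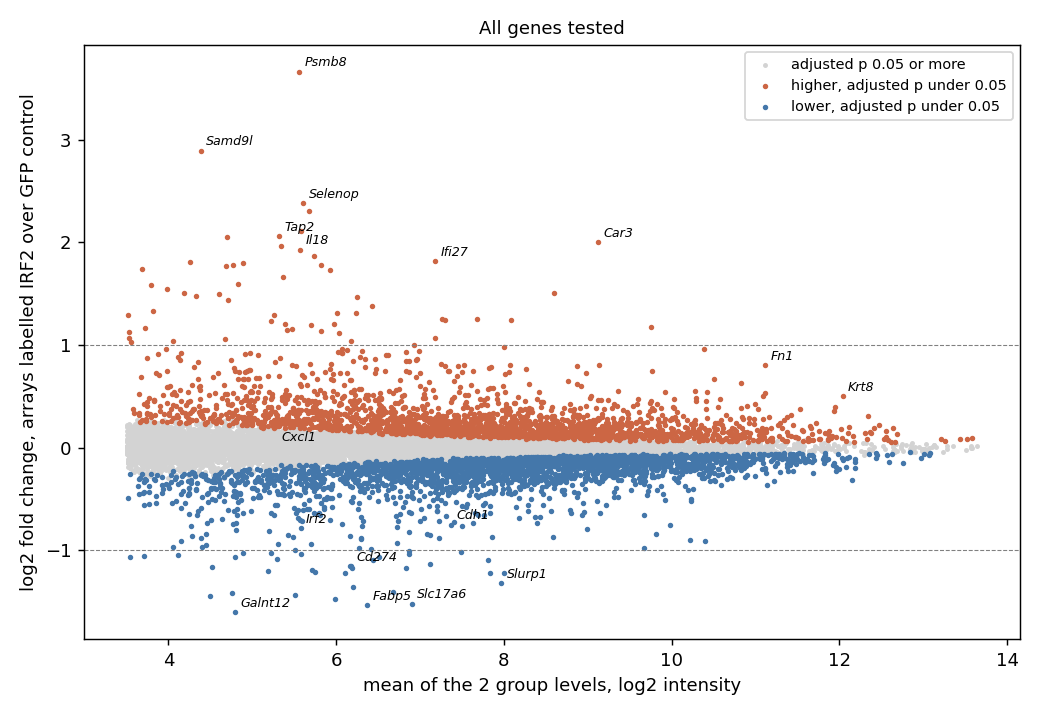
Log2 fold change of each of the 12795 genes tested (vertical axis, arrays labelled IRF2 over GFP control, 3 arrays each) against the mean of the log2 intensities of the 2 group levels (horizontal axis); red and blue points had an adjusted p under 0.05, and dashed lines mark 2-fold changes. Psmb8 lies highest at 3.67 and Galnt12 lowest among the labelled genes at -1.61.

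The largest rise among the genes named by the rule was in Psmb8, a catalytic subunit of the immunoproteasome, which read 13.4 ± 3.7 on the GFP control arrays and 166 ± 7.77 on the arrays labelled IRF2 (12.7-fold; log2 fold change 3.67, SE 0.14, adjusted p = 3.49e-11). It was followed by Samd9l, an interferon-induced gene (log2 fold change 2.90, SE 0.09), Selenop, the plasma selenium carrier (2.39, SE 0.06), the cathepsin gene Ctso (2.31, SE 0.07) and Psmb9, another immunoproteasome subunit (2.11, SE 0.11). The other genes among the 15 largest rises were Tap2, Parp14, Car3, Nmi, Il18, Igtp, Ifi27, Lgals9, Tlr3 and Serpinb9, with log2 fold changes between 1.78 and 2.06. Car3, a carbonic anhydrase, was the brightest of them, at 279 ± 4.67 against 1117 ± 16.7 (SD, n = 3 each). Several of these genes were dim on the GFP control arrays, and their folds depend on how low values are treated: with 16 added before the log, Samd9l came to 1.62, Parp14 to 1.26, Lgals9 to 1.15 and Tlr3 to 1.11. In the mean of all probe sets of a gene, Psmb8 came to 1.94, Ctso to 1.12, Serpinb9 to 1.10 and Parp14 to 1.04. Each of these genes has 2 probe sets, of which 1 lies above the intensity filter, so these means take in a dim probe set.

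The largest falls were smaller in size. Galnt12, a glycosyltransferase that starts mucin-type O-glycans, fell from 48.1 ± 1.41 to 15.9 ± 1.94 (SD, n = 3 each; log2 fold change -1.61, SE 0.09, adjusted p = 2.56e-09). It was followed by Fabp5, a fatty acid-binding protein (-1.53, SE 0.06), the glutamate transporter gene Slc17a6 (-1.52, SE 0.05), Acsl6, an acyl-CoA synthetase (-1.48, SE 0.07), and Bcat1, a branched-chain aminotransferase (-1.44, SE 0.08). Rgs2, Mpzl2, Fbxo2, Slurp1, Spint2, Mapk12, Phlda2, Bspry, Prkcz and Krt34 completed the 15 largest falls, with log2 fold changes between -1.44 and -1.20. Slurp1, a secreted Ly6 family protein, went from 396 ± 16.7 to 158 ± 4.88, and Spint2, an inhibitor of membrane serine proteases, from 348 ± 4.36 to 149 ± 5.39 (SD, n = 3 each). The 2 bright probe sets of Prkcz disagreed in sign, with changes of -1.20 and 0.25. Those of Bcat1 ran from -1.44 to -0.03, and those of Mapk12 from -1.23 to -0.30. In the mean of all probe sets, Prkcz came to -0.34, Bspry to -0.57, Mapk12 to -0.77, Bcat1 to -0.78 and Acsl6 to -0.81, and with 16 added before the log Galnt12 came to -1.01, Mpzl2 to -0.89 and Bcat1 to -0.84.

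MHC class I antigen processing and presentation genes were higher on the arrays labelled IRF2. Of 15 measured members, 12 rose and 1 fell, with a median log2 fold change of 0.71. Besides Psmb8 and Psmb9, the peptide transporter genes Tap2 (log2 fold change 2.06, SE 0.08) and Tap1 (1.44, SE 0.14), the peptide-trimming protease Erap1 (1.47, SE 0.06), the third immunoproteasome subunit Psmb10 (0.74, SE 0.05) and the proteasome activator Psme1 (0.74, SE 0.03) rose. The abundant genes of the complex itself rose less: B2m, the light chain, went from 1848 ± 25.6 to 2672 ± 86.9 (0.53, SE 0.02), and the heavy chain genes H2-D1 and H2-K1, whose near-identical relatives can share probes, were higher by 0.31 and 0.28 (SE 0.02 each; 0.19 and 0.50 in the mean of their probe sets). Tapbp, the tapasin gene, fell by 0.17 (SE 0.03), and the chaperone gene Calr, at 0.04 (SE 0.03, adjusted p = 0.283), was 1 of the 2 members that did not pass, although it passed without the replicate 3 array labelled IRF2 (0.07, adjusted p = 0.0444; range over all alternatives 0.0444 to 0.897). With 16 added before the log, Tap1 came to 0.89. The counts were the same adjusted over the list alone. Camera called the list higher (adjusted p = 2.04e-10), and this call held with an estimated correlation (adjusted p = 0.038).

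Interferon-stimulated genes moved in both directions, with more of them higher. Of 33 measured type I interferon-stimulated genes, 21 rose and 4 fell (the same adjusted over the list alone), with a median log2 fold change of 0.42 (0.27 with 16 added before the log). Parp14 (2.06, SE 0.10), Nmi (1.97, SE 0.09), Ifi27 (1.81, SE 0.05), the RNA sensor gene Ifih1 (1.38, SE 0.05) and Lgals3bp (1.25, SE 0.04) rose, whereas Ifit3 (-0.54, SE 0.09), Ifit2 (-0.50, SE 0.08), Oasl1 (-0.35, SE 0.06) and Samhd1 (-0.17, SE 0.04) fell. The call of Samhd1 was lost in the mean of its probe sets (-0.07, adjusted p = 0.281), and Ifit3 came to -0.26 with 16 added before the log. Rsad2, an antiviral gene, differed by -0.13 (SE 0.08, adjusted p = 0.215), and passed without the intensity trend (adjusted p = 0.0366, the lowest over its alternatives, of which the highest was 0.403). Camera called the list higher (adjusted p = 7.96e-08), but not with an estimated correlation (adjusted p = 0.0882). Of 12 measured interferon gamma-induced genes, 6 rose and 2 fell, the same adjusted over the list alone. The GTPase genes Igtp (1.86, SE 0.07) and Gbp7 (1.49, SE 0.09, and 0.65 in its other probe set) and the inflammatory caspase gene Casp1 (1.77, SE 0.11) rose. Cd274, which encodes the checkpoint ligand PD-L1, fell from 108 ± 4.39 to 48.4 ± 0.689 (log2 fold change -1.16, SE 0.06, adjusted p = 5.76e-10), and the chemokine gene Cxcl10 fell by 0.77 (SE 0.10). This list was called higher by camera (adjusted p = 0.0249), but not with an estimated correlation (adjusted p = 0.229) or under the stricter intensity filter (adjusted p = 0.315, the highest over its alternatives, of which fry gave the lowest, 3.64e-04). With 16 added before the log, Casp1 came to 1.08, Gbp7 to 0.90 and Cxcl10 to -0.42. Of the 8 measured immune cell markers, Cd14 alone passed, at 0.18 (SE 0.06, adjusted p = 0.035), and its call was lost in 4 of the 6 runs that left out 1 array.

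**Figure D2:**
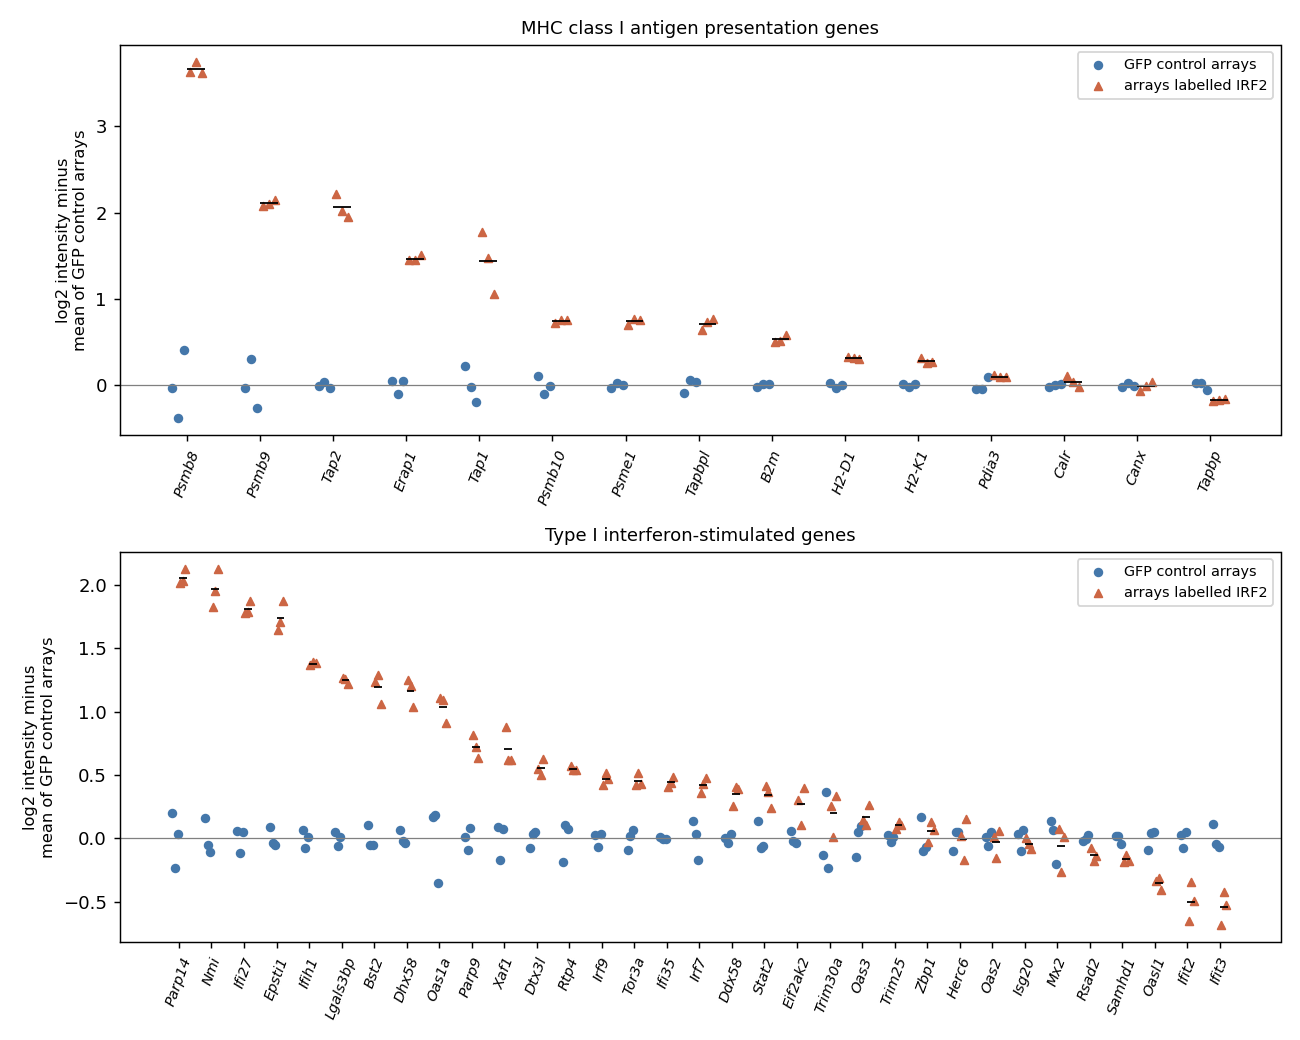
Log2 intensity of each measured MHC class I antigen presentation gene (top) and type I interferon-stimulated gene (bottom), per array, minus the mean of the 3 GFP control arrays; circles are GFP control arrays, triangles are arrays labelled IRF2, and short black lines are the means of the latter. Psmb8 sits at 3.67, and Ifit2 and Ifit3 lie below 0.

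The ligands of the chemokine receptor CXCR2, which draws neutrophils and related myeloid cells, were dim for the most part: 4 of the 6 lay under the intensity filter. Cxcl3 read 5.71 ± 0.884 on the GFP control arrays and 4.10 ± 0.0659 on the arrays labelled IRF2 (SD, n = 3 each). Both lie within the range of the tryptophan control probe sets (3.69 to 6.52) and under the intensity filter, so Cxcl3 had no test in the filtered data; in the test of all genes without the filter its adjusted p was 0.00339, lower on the arrays labelled IRF2. Cxcl2, Cxcl5 and Cxcl15 read 3.94 ± 0.342, 5.38 ± 0.446 and 8.15 ± 0.697 on the GFP control arrays (SD, n = 3 each) and were also under the filter, with adjusted p of 0.871, 0.113 and 0.255 without it. Of the 2 ligands above the filter, Cxcl1 read 38.9 ± 1.36 and 39.2 ± 2.15 (log2 fold change 0.01, SE 0.07, adjusted p = 0.946; its sign turned under quantile normalization and in the mean of its probe sets), and Ppbp fell by 0.45 (SE 0.07, adjusted p = 5.73e-05). Camera gave these 2 genes an adjusted p of 0.340.

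Among other chemokines and inflammatory cytokines, 7 of 19 measured genes rose and 3 fell. Il18, an inflammasome-processed cytokine, rose by 1.93 (SE 0.15), the macrophage growth factor Csf1 by 0.68 (SE 0.07) and the alarmin Il33 by 0.60 (SE 0.04), while the T cell chemoattractant Ccl5 fell by 0.75 (SE 0.09). Csf1 came to 0.33 in the mean of its probe sets, and Ccl5 to -0.47 with 16 added before the log. Camera did not call this list (adjusted p = 0.0676), but called it higher under the stricter intensity filter (median 0.32 in place of 0.10, adjusted p = 0.0032), without chromosome 8 genes (0.02), without the replicate 3 GFP control array (0.0424) and without the replicate 2 array labelled IRF2 (0.0447). Over its alternatives the adjusted p ran from 0.0032 to 0.315. Of 16 measured NF-kappaB targets, 2 rose and 2 fell, and the largest of these changes in size was 0.22 (SE 0.04) for Tnfaip2; the list had an adjusted p of 0.886.

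Epithelial, mesenchymal and matrix genes changed in both directions. Of 21 measured intestinal epithelial markers, 3 rose and 4 fell. The adhesion genes Epcam, Cdh1 and Cdh17 fell, with log2 fold changes of -0.81 (SE 0.11), -0.75 (SE 0.04) and -0.57 (SE 0.03). Epcam came to -0.43 in the mean of its probe sets, and to -0.04 in its other probe set. The abundant keratin gene Krt8 rose by 0.50 (SE 0.02), from 3533 ± 32.7 to 4999 ± 114. Camera did not call that list (adjusted p = 0.405). In the epithelial-mesenchymal transition list, 9 of 20 rose and 6 fell (camera adjusted p = 0.0898). The matrix genes Sparc (1.73, SE 0.07; 1 of its 3 bright probe sets gave -0.0094), Fn1 (0.80, SE 0.02) and Tgfbi (0.54, SE 0.04) rose, and Tnc fell by 0.43 (SE 0.03). Of 25 matrix and adhesion genes, 10 rose, among them Timp3 (0.63, SE 0.03) and Thbs1 (0.39, SE 0.02), and 4 fell, among them the collagenase gene Mmp13, by 0.74 (SE 0.05). Camera called this list higher (adjusted p = 0.0258), but not with an estimated correlation (adjusted p = 0.393, the highest over its alternatives, of which fry gave the lowest, 0.0039). The call was also lost without the replicate 1 array labelled IRF2 (adjusted p = 0.0644), under the stricter filter (0.0566) and without the intensity trend (0.0627). Of 11 fibroblast and stromal markers, 4 rose, with Pdgfra at 0.70 (SE 0.10; 0.36 in the mean of its probe sets), and 2 fell, with Mgp at -0.28 (SE 0.03; camera adjusted p = 0.393). Of 6 endothelial markers, Egfl7 alone passed, at -0.22 (SE 0.07, adjusted p = 0.0315), and its call was lost in 3 of the 6 runs that left out 1 array.

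More cell cycle genes fell than rose, and more cholesterol and hypoxia genes rose than fell. Of 36 cell cycle genes, 19 fell and 2 rose. The replication genes Cdc6 (-0.37, SE 0.04), Mcm5 (-0.29, SE 0.02) and Mcm7 (-0.23, SE 0.02) fell, and the mitotic cyclin gene Ccnb2 rose by 0.14 (SE 0.02); the median over the list was -0.08. Camera called the list lower (adjusted p = 6.43e-04), but not with an estimated correlation (adjusted p = 0.315). Of 17 cholesterol biosynthesis genes, 10 rose, Hmgcs1 by 0.27 (SE 0.03) and Sqle by 0.23 (SE 0.02) among them, and 1 fell. That list was called higher (adjusted p = 0.0018), but not with an estimated correlation (adjusted p = 0.229). Of 18 hypoxia and glycolysis genes, 8 rose and 2 fell. The angiogenic factor Vegfa rose by 0.69 (SE 0.05, and 0.37 in its other probe set). Bnip3 rose by 0.36 (SE 0.03) and Pfkl by 0.42 (SE 0.04), and P4ha2 fell by 0.46 (SE 0.04). Camera called the hypoxia list higher (adjusted p = 0.0258), but not with an estimated correlation (adjusted p = 0.229) or without the intensity trend (adjusted p = 0.0972). The lowest adjusted p over its alternatives, 9.06e-04, came from fry, and the highest was 0.229.

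Target genes of signalling and stress pathways were also examined. Of 22 MAPK output genes, 9 rose and 5 fell; Dusp6 (-0.32, SE 0.02) and Egr1 (-0.30, SE 0.03) fell, and Hbegf and Ier3 rose by 0.27 and 0.20 (SE 0.02 each). Camera gave an adjusted p of 0.264. Of 18 Wnt/beta-catenin targets, 7 rose and 2 fell; the largest rises were in the secreted Wnt antagonists Dkk1 (1.51, SE 0.09; 0.80 with 16 added before the log) and Wif1 (0.90, SE 0.06), and the list had an adjusted p of 0.0587. It was called higher under quantile normalization (adjusted p = 0.0399), without chromosome 8 genes (0.039), without the replicate 1 GFP control array (0.0421) and without the replicate 2 array labelled IRF2 (0.0447). Over its alternatives the adjusted p ran from 7.90e-04, given by fry, to 0.235, given by camera with an estimated correlation. Of 16 p53 targets, 6 fell, with Perp at -0.67 (SE 0.04) and the cell cycle inhibitor Cdkn1a at -0.44 (SE 0.04), and 2 rose (adjusted p = 0.129). Of 21 unfolded protein and amino acid stress genes, 10 fell, with Atf3 at -0.47 (SE 0.05) and Mthfd2 at -0.33 (SE 0.03), and 3 rose, with Pdia4 at 0.29 (SE 0.03), a call that was lost in the mean of its probe sets (0.11, adjusted p = 0.112). That list had a camera adjusted p of 0.0743, but was called lower with no filter (0.0349) and with the mean of probe sets (0.0245). Its lowest adjusted p over the alternatives, 0.00821, came from fry, and its highest, 0.408, from camera with an estimated correlation. Adjusted over the list alone, the counts of members past the threshold differed from those over all genes by at most 1 in each direction in each of the 20 fixed lists, and Cd14 and Egfl7 no longer passed.

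**Figure D3:**
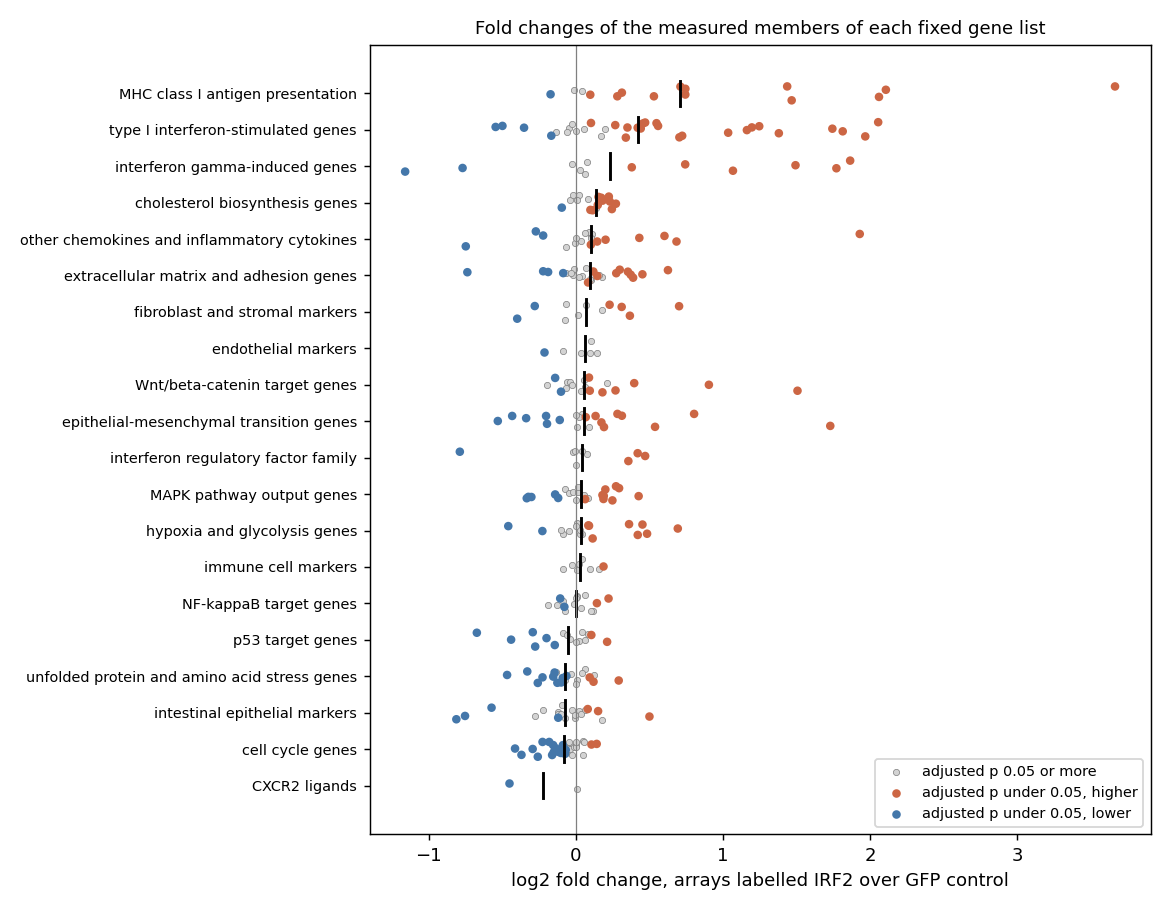
Log2 fold change (horizontal axis, arrays labelled IRF2 over GFP control) of every measured member of the 20 fixed gene lists, one list per line; red and blue points had an adjusted p under 0.05, grey points did not, and black lines are list medians. The MHC class I list has the highest median, 0.71.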

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

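All of the alternatives listed before the data were examined were run. The robust setting kept the reported list tests, and testing each probe set on its own held no list test, so neither bears on the lists. Leaving out the genes of chromosome 8 was added after seeing the data. Counts of genes and lists stayed within 1.5 times the reported ones except as follows. Genes at least 2-fold higher numbered 34 under the filter at the 60th percentile, which tests fewer genes, and 29 with log2(value + 16), which also gave 13 genes at least 2-fold lower. Testing each probe set on its own gave 3234 higher and 3959 lower probe sets, since it counts several per gene. Lists called lower numbered 2 with no filter and 2 with the mean of a gene's probe sets. Camera with an estimated correlation called 1 list higher and 0 lower, against 6 and 1 at the preset correlation, and fry, which has no comparison with other genes, called 12 higher and 5 lower. For the setting without chromosome 8, the counts were 2053 higher and 2203 lower. Leaving out 1 array at a time gave 1772 to 1982 genes higher, 2075 to 2478 lower, 56 to 62 at least 2-fold higher and 33 to 39 at least 2-fold lower; Irf2 lay between -0.81 and -0.76, and lists called higher numbered 5 to 8, with 1 lower in each run. The replicate numbers do not pair the arrays: the deviations of same-numbered arrays from their group means correlated across genes at 0.0722, -0.0763 and -7.71e-04. With the replicate number as a block, 2141 genes were higher and 2537 lower, 4530 of the genes called in the fit without it kept their call and sign, and 7 lists were higher, the Wnt/beta-catenin list added (adjusted p = 0.0426); 1 of the 3 GFP control arrays correlated best with its own number. Directions turned only where the reported value was not called. Cxcl1 came to -0.00711 under quantile normalization, -0.0011 in the mean of its probe sets, and between -0.0344 and 0.0425 over runs that left out 1 array. The direction camera gave to the endothelial list turned, with list medians of -0.0557 under the 60th percentile filter, 0.0485 under quantile normalization, 0.0355 in the mean of probe sets and 0.0355 without chromosome 8, and of 0.0258 to 0.0938 over runs that left out 1 array. For NF-kappaB targets these runs gave medians of -0.0341 to 0.0395. The causes of these turns were not tested. Low signal limits what can be read from Cxcl3 and the other CXCR2 ligands under the intensity filter.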

Other observations

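The 5 gene lists of the next paragraph were chosen after the largest changes had been seen, as were the tests of immune cell markers, of mislabelled arrays and of neighbouring genes with list members kept; the chromosome 8 tests were chosen after a scan along all chromosomes.

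Further genes of lysosomal proteolysis and pyroptosis differed between the groups. Of 16 measured cathepsins and related genes, 6 rose and 3 fell: Ctso rose by 2.31 on the log2 scale, Ctss by 1.59, Lgmn by 0.76 and Ctsl by 0.30, and Ctsh fell by 1.17. Of 10 inflammasome and pyroptosis genes, Il18 (1.93), Casp1 (1.77), the pore-forming gasdermin gene Gsdmd (1.25) and Casp4 (0.74) rose and Gsdme fell by 0.26, while Il1b differed by 0.11 (adjusted p = 0.343). In contrast to the immunoproteasome subunits, the constitutive proteasome genes were lower: 24 of 31 fell and 0 rose, by small amounts, with Psmb3 at -0.23, Psmb5 at -0.09 and Psmb6 at -0.09. Camera called that list lower (adjusted p = 2.62e-08), but not with an estimated correlation (adjusted p = 0.0556). The camera adjusted p in this paragraph are over these added lists alone, not over the fixed lists. As the added lists were chosen after the largest changes had been seen on the same arrays, these values describe the lists. They are no independent test of a shift. The inflammasome list holds Il18 and the cathepsin list holds Ctso, both among the largest rises. The inflammasome list (adjusted p = 0.0193 at the preset correlation, 0.119 with an estimated one) and the cathepsin list (0.0698 and 0.124) were not called with an estimated correlation. Of 6 complement genes 4 rose, with C1ra at 1.30, and 1 fell (0.0562 and 0.119). Of 28 epithelial adhesion and polarity genes, 12 fell, among them Lad1 (-0.84), Esrp2 (-0.47) and Crb3 (-0.43), and 4 rose. A wider fall of such genes beside Epcam and Cdh1 was expected to give a camera p under 0.05 before adjustment. Camera gave 0.0506 (adjusted p = 0.0632), so this expectation was not met. A value this near the threshold does not show that such a fall is absent.

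Fold changes followed position along some chromosomes. Of 629 windows of 20 consecutive genes, 17 had a median log2 fold change beyond 0.15, against at most 2 in 1000 shuffled gene orders (permutation p = 0.001, the smallest they can give). On chromosome 8, 73.0% of 688 genes were lower on the arrays labelled IRF2. There, 33 of 34 windows had a median below 0, against 46.9% of the windows elsewhere. Measured from each gene's mean over the GFP control arrays, the chromosome lay 0.11 below other genes on 2 of the arrays labelled IRF2 and 0.12 below on the third. The GFP control arrays lay between -0.01 and 0.01, near 0 by construction, so these values do not tell which group departs. Gene length, signal level and local gene density do not account for the chromosome 8 shift. After regression on them it was -0.10 (95% interval over resampled genes, -0.12 to -0.09). On chromosome 5, 5 windows lay below -0.15 and 3 above 0.15. A candidate explanation is a copy number difference between the cultures of the 2 groups; GC content, shared regulation of neighbouring genes and an effect of IRF2 itself were not tested and stay open.

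The rise of MHC class I and interferon-stimulated genes was set against 4 explanations. Immune cells in the cultures are argued against by their markers, whose median log2 change was 0.0299 (95% interval -0.0254 to 0.156) and of which the brightest, Cd14, read 120 on the GFP control arrays and 137 on the arrays labelled IRF2. A copy number gain that reaches past Psmb8, Psmb9, Tap1 and Tap2 is argued against by the 20 nearest measured genes outside the fixed lists. Their median was 0.0191 (-0.0377 to 0.0829), and they ran from -0.17 (H2-Ke6) to 0.79 (H2-DMa). With list members kept, of which H2-K1 was 1 of the 20 nearest, the median was also 0.0191. A gain limited to Psmb8, Psmb9, Tap1 and Tap2 themselves would not be seen this way. A rise of all proteasome genes is argued against by the constitutive ones, at -0.10 (-0.13 to -0.08). Scaling between arrays left the MHC class I median at 0.70 or higher. A difference between the cultures that arose by chance in selection, without IRF2, stays open, since no label says how many cultures were made, and an effect of IRF2 may explain the rise only as a hypothesis.

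The lower Irf2 signal on the arrays labelled IRF2 was set against mislabelling and copy number. Single arrays swapped between groups are argued against, since the lowest correlation within groups (0.998) exceeded the highest between groups (0.9965). Whether all 3 arrays of one group carry the label of the other cannot be told apart from a probe set that reads only the cells' own transcript: the one probe set, at -0.79, has no known position. A copy number loss that spans Irf2 and its neighbours, on chromosome 8, does not reach this size. The 20 nearest measured genes outside the fixed lists had a median of -0.11 (95% interval -0.17 to 0.05), and ran from -0.50 (Dctd) to 1.78 (Tlr3). The median was the same with list members kept. A loss limited to Irf2 itself or to few genes beside it would not be seen this way. A fall of the endogenous transcript beside a transgene that the probes do not see may explain the lower Irf2 signal and was not tested.

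The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4642 genes at an adjusted p under 0.05 and 93 with at least a 2-fold change, and the highest of the other splits gave 0 for both (limma, with 142 to 356 genes at an unadjusted p under 0.05); 1 of the 10 splits, the real one, gave as many. For the fixed lists, camera at the preset correlation called 7 in the real split and at most 6 in the others. Each of the other splits sets 2 arrays of one group and 1 of the other against the rest, so it keeps part of the difference between the groups, and these counts do not show how many lists or genes chance alone would call.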
